A study of Homo sapiens with 3 samples.

How the data were processed

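RNA-seq libraries of the HCT116 colon cancer line, labelled p53 knockout, were grouped by the hours of 5-fluorouracil in their titles (0 h, 4 h and 12 h), with 1 library per group. The authors deposited 1 table per library with FPKM values (fragments scaled to transcript length and to the mapped total) for 47846 assembled loci, per the file headers. TopHat2, Cufflinks and the build hg19 are named in the submitters' processing notes, without versions. The annotation, the filters and the use of strand are not given in the sources used here. The header of each value column begins with WT, while the titles, genotypes and file names give a knockout. Of the loci, 28943 carry a gene name and 18903 do not. There were 4762 names on more than 1 locus and 1461 loci with several names. Among the genes named, PLK3, NOP16, FAS, CCNB2, LINC00152, SLC7A11 and LYZ lie on loci with a further name, and their values cover the whole locus.

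The depth per sample is unknown. Ratios between low values were searched for steps of whole reads, and the fullest bin of width 0.02 log2 units held 0.834% of loci for 4 h against 0 h and 0.593% for 12 h against 0 h, so no relative depth could be read. Total FPKM was 791920, 1085524 and 1043505 at 0 h, 4 h and 12 h, and the 10 highest loci held 21.7%, 22.9% and 30.4% of it. Loci at exactly 0 numbered 3539, 4772 and 1558. Across protein-coding genes on 1 expressed locus at 5 FPKM or more in both libraries, Pearson's r of log2 values was 0.940 (4 h and 0 h), 0.912 (12 h and 0 h) and 0.925 (12 h and 4 h). These are correlations across genes, which are not independent replicates.

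Ratios were computed as log2 of FPKM plus 1. Named loci with at least 1 FPKM in 1 library of the pair were counted as higher or lower at 2-fold. No p-value was computed, since no group has a replicate. Before the data were examined, 25 gene lists were fixed, and 24 had a measured member. They cover p53 targets, nucleotide metabolism, replication, G1/S regulators, mitosis, cohesion, recombination, histones, immediate early genes, ATF4 and unfolded protein stress, heat shock, NF-kB, interferon, apoptosis, snoRNA hosts, ribosome biogenesis, the RNA exosome, ribosomal proteins, cholesterol synthesis, nuclear long noncoding RNAs, colon, fibroblast, and blood and endothelial markers, mitochondrially encoded genes, and housekeeping transcripts. Older symbols were matched where the tables use them. A symbol on several loci was given the locus with the highest median. Each list's median was given a percentile among 10000 random lists of the same size drawn within 20 expression bins. It was also given a 95% interval over genes, taken from the ranked log2 ratios of its members by the binomial distribution. The percentile describes these libraries and is not a test between conditions. A coding gene on 1 expressed locus has exactly 1 locus that reaches 1 FPKM in any library and lies above 0 in all 3, while its symbol can also stand on loci below 1 FPKM.

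The named genes were fixed by rule. They are TP53, DDX11-AS1 and DDX11, the 8 highest and 8 lowest ratios per comparison among genes at 5 FPKM or more other than small-RNA genes, and up to 4 members of each list with the largest ratios. A gene named for 1 comparison may appear in others. Of the loci with extreme ratios, only some are printed. The 20 highest and lowest protein-coding genes on 1 expressed locus were listed after the data were seen, and examples named from them were chosen after their values were seen, as were TYMS and TP73 and the p53 targets MDM2, GDF15 and SESN1 where the rule does not take them.

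Alternatives fixed beforehand were pseudocounts of 0.1 and 5, a minimum of 5 FPKM or no minimum, folds of 1.5 and 3, centring on the median, upper-quartile scaling, and leaving out small-RNA genes with totals made equal. In the last, the total was summed over named loci other than small-RNA genes, so unnamed loci were left out of it too. The effect of making totals equal was not separated from that of leaving out small-RNA genes. Alternatives added after the data were seen were coding genes on 1 expressed locus, unnamed loci included, zeros left out, the locus with the highest mean, fused loci left out, and random lists matched also on length. The length-matched setting also cut each list to its coding members on 1 expressed locus. Lists of YAP targets and of SRF and actin cytoskeleton genes were written after the leading genes had been seen. Gene span, transcript length and coding status came from GENCODE release 29, matched by symbol. Its build differs from hg19, so no coordinates are given. Lengths were found for 7172 of 7174 genes.

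The counting and list steps were tested on simulated data. With a noise SD of 0.2 log2 units against the 0 h library, 200 changed genes among 9455 were recovered at 0%, 36%, 99% and 100% for folds of 1.5, 2, 3 and 4, with 0 false calls. That noise was assumed, since no replicate measures it, and the 2-fold limit lies far outside it, so the run shows only that the arithmetic is right and gives no error rate for these libraries. Of 100 random lists of 30 genes, 6% lay outside the central 95%. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.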

Results

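RNA-seq was made from total RNA of HCT116, a human colon cancer line, of a derivative labelled p53 knockout. Cells were left untreated (0 h) or exposed to 350 µM 5-fluorouracil, a uracil analogue that inhibits thymidylate synthase and is built into RNA and DNA, for 4 h or 12 h. Each of the 3 groups holds 1 library, so no difference has a replicate check, no test between conditions was possible, and every value describes these libraries. The values are FPKM for 47846 assembled loci, and 15063, 14905 and 15052 of them reached 1 FPKM at 0 h, 4 h and 12 h. The number of reads behind the values is unknown. Log2 ratios are of FPKM plus 1, which understates the change of low genes. A gene was counted as higher or lower when it differed at least 2-fold on that scale and reached 1 FPKM in at least 1 library of the pair.

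The study concerns CONCR, a long noncoding RNA listed under the symbol DDX11-AS1, and its neighbour DDX11, a DNA helicase with a role in sister chromatid cohesion. TP53, the gene the labels give as knocked out, was listed at 37.3 FPKM at 0 h, 38.6 at 4 h and 27.3 at 12 h. A value for the whole gene also covers exons outside a deletion, so it does not check the label. Target genes of p53 were higher after treatment, as given for each comparison, and the column header of each deposited table begins with WT, against the label. The libraries are therefore called libraries labelled p53 knockout throughout. CONCR was listed at 2.27, 3.43 and 2.35 FPKM at 0 h, 4 h and 12 h, and DDX11 at 23.7, 29 and 19.7. Neither gene differed 2-fold between any pair of libraries. Whether strand was used in the counting is not given in the sources used here, so reads of CONCR and of genes on the opposite strand may not be separated.

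The first comparison asked what differed after 4 h of drug. In the library labelled p53 knockout and treated for 4 h, growth-response and p53 target genes were higher than in the untreated one, and genes of mitosis were lower as a group. Of 32 immediate early genes counted, which respond within minutes to hours to growth signals and stress, 14 were at least 2-fold higher and 0 lower. CYR61, a secreted matrix protein, was at 4.05 FPKM at 0 h and 61.7 at 4 h, and CTGF, a related protein, at 0.469 and 9.74. The transcription factor genes FOSL1 (21.6 and 131 FPKM) and MAFF (2.38 and 16.3) were also higher. Of 35 p53 targets counted, 14 were higher and 0 lower, among them the kinase genes PLK2 (11.8 and 55.1 FPKM) and PLK3 (9.85 and 30.1), the antiproliferative gene BTG2 (14.2 and 43.9) and the exonuclease gene AEN (12.4 and 41.7).

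Of 21 regulators of the G1 to S transition, 4 were higher and 0 lower at 4 h. These were the cyclin genes CCNE2 (5.22 and 16.6 FPKM), CCND1 (106 and 232) and CCND3 (7.6 and 17.3) and the phosphatase gene CDC25A (5.47 and 14.0). Of 42 genes of mitosis and G2/M, 0 passed 2-fold, yet 35 had a log2 ratio below 0. The kinesin gene KIF20A was at 23.7 FPKM at 0 h and 11.7 at 4 h, and the centromere gene CENPF at 21 and 11. Of 31 apoptosis regulators, 6 were higher and 0 lower, including PMAIP1, which encodes the BCL2-family protein NOXA (30.6 and 83.1 FPKM), and CFLAR, an inhibitor of caspase 8 (17.0 and 45.3). Of 16 NF-kB targets and cytokines, 4 were higher and 1 lower. RELB, an NF-kB subunit, was at 2.16 and 13.9 FPKM and the cytokine gene LIF at 9.67 and 27.9, while SOD2, the mitochondrial superoxide dismutase, was at 245 and 69.9. Of 16 nuclear long noncoding RNAs, 5 were higher and 0 lower, among them MIR22HG (1.37 and 10.1 FPKM), LINC00152 (16.0 and 47.0) and PVT1 (59.2 and 128). All 43 genes of ribosome biogenesis had a log2 ratio above 0 as deposited, against 38 after centring on the median, 39 with upper-quartile scaling and 24 with small-RNA genes left out and totals made equal, and 0 passed 2-fold, with GAR1 at 11.2 and 23.2 FPKM and NOP16 at 13.0 and 24.2. With small-RNA genes left out, the median log2 ratio of named loci at 5 FPKM or more was itself -0.23.

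The median log2 ratio of named loci at 5 FPKM or more in both libraries was 0.15 at 4 h, so list medians are also given relative to it. Each median was placed among 10000 random lists of the same size matched on expression. Immediate early genes had a median of 0.79 (0.64 relative to the shift, percentile 100) and p53 targets of 0.77 (0.62 relative, percentile 100). The median was 0.51 for G1/S regulators (0.35 relative, percentile 99.95), 0.50 for NF-kB targets (0.34 relative, percentile 99.99) and 0.43 for nuclear long noncoding RNAs (0.28 relative, percentile 99.41). It was 0.40 for ribosome biogenesis (0.24 relative, percentile 99.98) and 0.35 for apoptosis regulators (0.19 relative, percentile 99.82). The medians, with small-RNA genes left out and totals made equal, were 0.12 for G1/S regulators, 0.13 for NF-kB targets, 0.094 for nuclear long noncoding RNAs, 0.022 for ribosome biogenesis and -0.013 for apoptosis regulators. That scaling put the median of named loci at 5 FPKM or more at -0.23, and these medians are not given relative to it. As deposited, mitosis genes lay at -0.34 (-0.50 relative to the shift of 0.15, percentile 0). Replication-dependent histones lay at -0.39 (-0.54 relative, percentile 2.06), with 13 of 53 listed genes measured, at low values and with copies that share reads. Cholesterol synthesis genes lay at -0.099 (-0.25 relative, percentile 0.09), and cytosolic ribosomal proteins at 0.062, which became -0.093 relative to the shift (percentile 0.09). Ribosomal protein genes share reads with many pseudogene copies. Intervals over genes included 0 for NF-kB targets (-0.13 to 0.96), nuclear long noncoding RNAs (-0.064 to 1.10) and apoptosis regulators (-0.028 to 0.76). They also included 0 for cholesterol synthesis (-0.18 to 0.063) and ribosomal proteins (-0.038 to 0.12), whose intervals lay wholly below the shift of 0.15. Those of the other lists given here did not include 0. That of G1/S regulators (0.14 to 0.66) included the shift.

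Several groups stayed inside the central 95% of random lists at 4 h. Nucleotide metabolism, which includes the drug's target, had a median of 0.18 with 0 of 32 genes past 2-fold. Sister chromatid cohesion had a median of 0.045 with 0 of 25 past 2-fold. Replication licensing and fork genes (0.25), recombination and Fanconi repair (0.22), snoRNA host genes (0.33), the RNA exosome (0.20), heat shock (0.13), the ATF4 and unfolded protein list (0.075) and interferon response (-0.0038) were also inside, as were colon epithelial markers (0.23), fibroblast markers (-0.016, 6 measured) and housekeeping transcripts (0.15). Of the blood and endothelial markers only LYZ was listed at 1 FPKM or more, on a locus that also carries the name CPSF6, so its value cannot be read as LYZ. No mitochondrially encoded gene was measured.

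**Figure D1:**
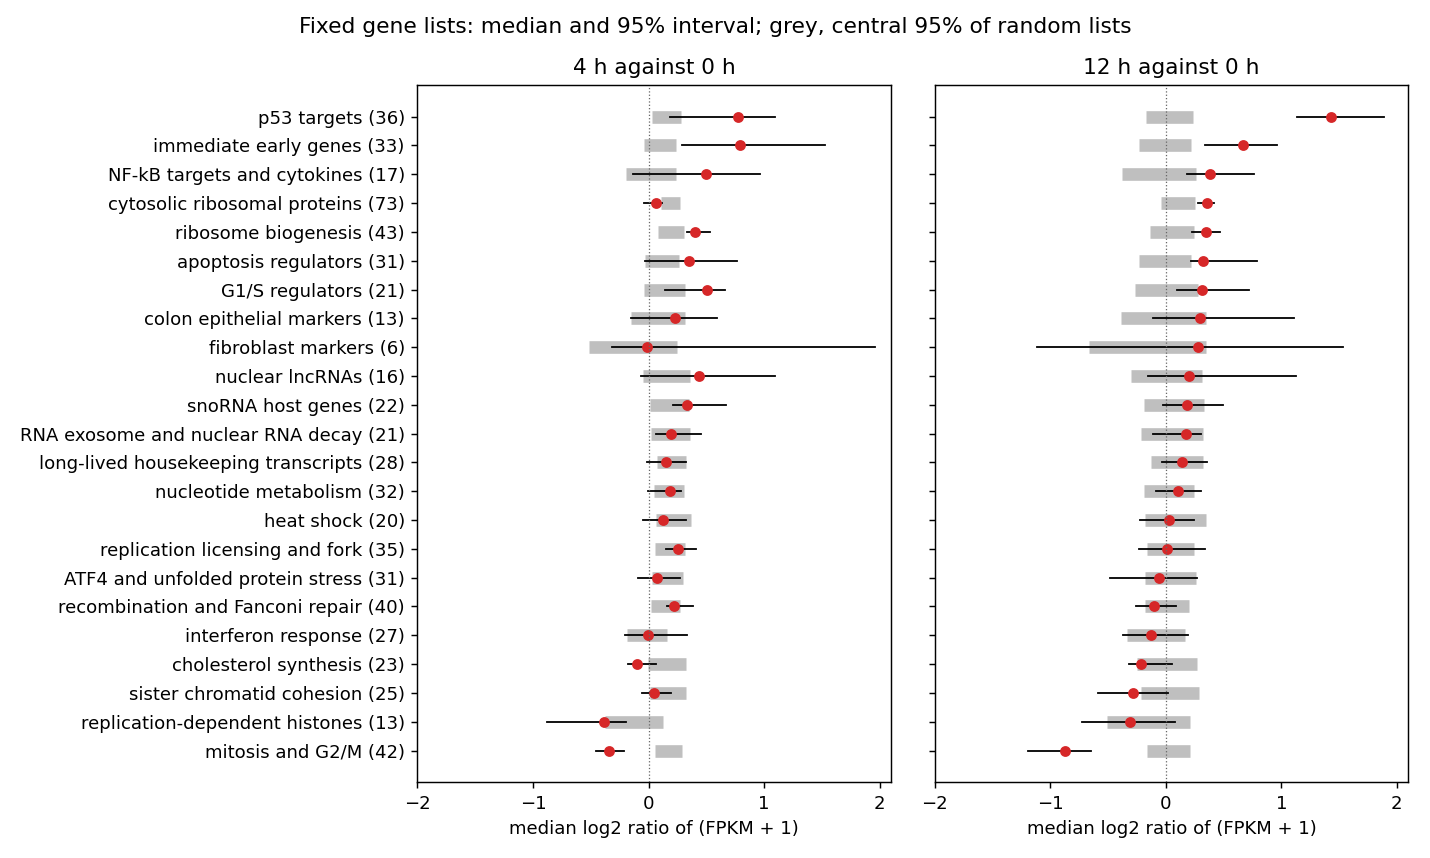
Median log2 ratio of (FPKM + 1) of each fixed gene list, with the number of measured genes in brackets, for the 4 h and 12 h libraries against the 0 h library. Points are medians, black lines are 95% intervals over genes from the ranked members, and grey bars are the central 95% of 10000 expression-matched random lists. The p53 target list lies at 0.77 and 1.43 and the mitosis list at -0.34 and -0.87.

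Over all named loci, 715 were at least 2-fold higher and 345 lower at 4 h, of 14827 counted. The split depends on scaling, since centring on the median gave 520 higher and 527 lower. Leaving out small-RNA genes with totals made equal gave 431 and 907, of 15513 counted. That setting rescales each library, so its split cannot be put down to small-RNA genes alone. Among protein-coding genes on 1 expressed locus, meaning a single locus at 1 FPKM or more whatever other loci share the symbol, a class chosen after the data were seen, 315 were higher and 111 lower, of 9336. Among the loci with extreme ratios, the one named ENPP7P5 and LINC00937 was at 0.59 FPKM at 0 h and 10788 at 4 h, and FGF13 was at 2576 at 0 h and listed at 0 at 4 h. Exactly the same 0 h value as that of FGF13 stood at 4 loci in all. The 10788 lies near a multiple of a 4 h value repeated at 5 loci. Neither ratio is therefore read as a change in expression.

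The second comparison set 12 h of drug against the untreated library. In the library labelled p53 knockout and treated for 12 h, 26 of 36 p53 targets were at least 2-fold higher than at 0 h and 0 were lower. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was at 47.7 FPKM at 0 h and 345 at 12 h. The death receptor gene FAS was at 5.85 and 36.6, PHLDA3, an inhibitor of AKT signalling, at 3.73 and 24.6, and the translesion polymerase gene POLH at 9.74 and 46.6. Of 42 genes of mitosis and G2/M, 17 were at least 2-fold lower and 0 higher. HMMR, a spindle protein gene, was at 11.9 FPKM at 0 h and 1.95 at 12 h, CENPF at 21.0 and 4.91, KIF20A at 23.7 and 5.75, and the cyclin gene CCNB2 at 70.3 and 18.5.

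Genes of sister chromatid cohesion, the process in the study's title, had a median log2 ratio of -0.29 at 12 h (95% interval over genes -0.59 to 0.017, percentile 0.47), and 2 of 25 were 2-fold lower and 0 higher. These were RAD21, a subunit of the cohesin ring (243 and 109 FPKM), and SGO2, a protector of centromeric cohesin (8.98 and 2.61). The cohesin regulators PDS5B (15.9 and 7.70) and PDS5A (162 and 87.5) had log2 ratios of -0.96 and -0.88. Of 35 genes of replication licensing and fork, 1 was higher and 1 lower. PCNA, the sliding clamp and also a p53 target, was at 167 and 481 FPKM, and the helicase subunit gene MCM3 at 48.3 and 23.5. Of 21 G1/S regulators, 4 were higher and 1 lower, with CCNE2 at 5.22 and 24.1 FPKM and CCNE1 at 27.7 and 67.9. Of 32 immediate early genes, 10 were higher and 0 lower, with ATF3 at 6.55 and 29 FPKM. Of 31 apoptosis regulators, 7 were higher and 0 lower, FAS again among them, with PMAIP1 at 30.6 and 116 FPKM and BBC3, which encodes PUMA, at 5.95 and 17.4. The apoptosis and p53 target lists share members such as FAS, so their counts are not independent.

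The shift of named loci was 0.055 at 12 h. The p53 target median was 1.43 (95% interval over genes 1.13 to 1.89, percentile 100) and the mitosis median -0.87 (-1.19 to -0.65, percentile 0). The median was 0.67 for immediate early genes (percentile 100), 0.35 for ribosome biogenesis (percentile 99.95), 0.32 for apoptosis regulators (percentile 99.82) and 0.31 for G1/S regulators (percentile 98.85). NF-kB targets had a median of 0.39 (percentile 99.70) and cytosolic ribosomal proteins of 0.36 (percentile 100). Leaving out small-RNA genes with totals made equal gave medians of 0.056 for ribosome biogenesis, 0.069 for apoptosis regulators, 0.048 for G1/S regulators, 0.13 for NF-kB targets and 0.068 for ribosomal proteins, while p53 targets lay at 1.21, immediate early genes at 0.56 and mitosis genes at -1.16. Under that scaling the median of named loci at 5 FPKM or more was -0.22, and these medians are not given relative to it. Genes with a long span had lower ratios at 12 h. The median log2 ratio was 0.30 over 1008 coding genes under 10 kb and -0.24 over 1262 genes from 100 to 300 kb. Random lists matched on gene span and transcript length as well, an alternative chosen after the data were seen, put the coding members of the mitosis list on 1 expressed locus at percentile 0, those of the p53 target list at 100 and those of the cohesion list at 0.86. The same matching put such members of the ribosomal protein list (58) at percentile 95.87 and of the NF-kB list (11) at 86.95, inside the random range.

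Nucleotide metabolism again had 0 genes past 2-fold at 12 h (median 0.11), with RRM2, a ribonucleotide reductase subunit, at 76.4 FPKM at 0 h and 148 at 12 h. TYMS, the thymidylate synthase gene, was at 113, 132 and 139 FPKM at 0 h, 4 h and 12 h. Other lists inside the random range were replication licensing and fork (0.013), recombination and Fanconi repair (-0.098), histones (-0.31), ATF4 and unfolded protein stress (-0.055), heat shock (0.028), interferon response (-0.13), snoRNA hosts (0.19), the RNA exosome (0.18), cholesterol synthesis (-0.21), nuclear long noncoding RNAs (0.20), colon epithelial markers (0.29), fibroblast markers (0.28) and housekeeping transcripts (0.14). HSP90AB1, a chaperone gene at 455 FPKM at 0 h and 441 at 4 h, and EZR, at 261 and 466, were listed at 0 at 12 h. An exact 0 for such abundant genes can be a failed estimate, so no ratio is given.

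**Figure D2:**
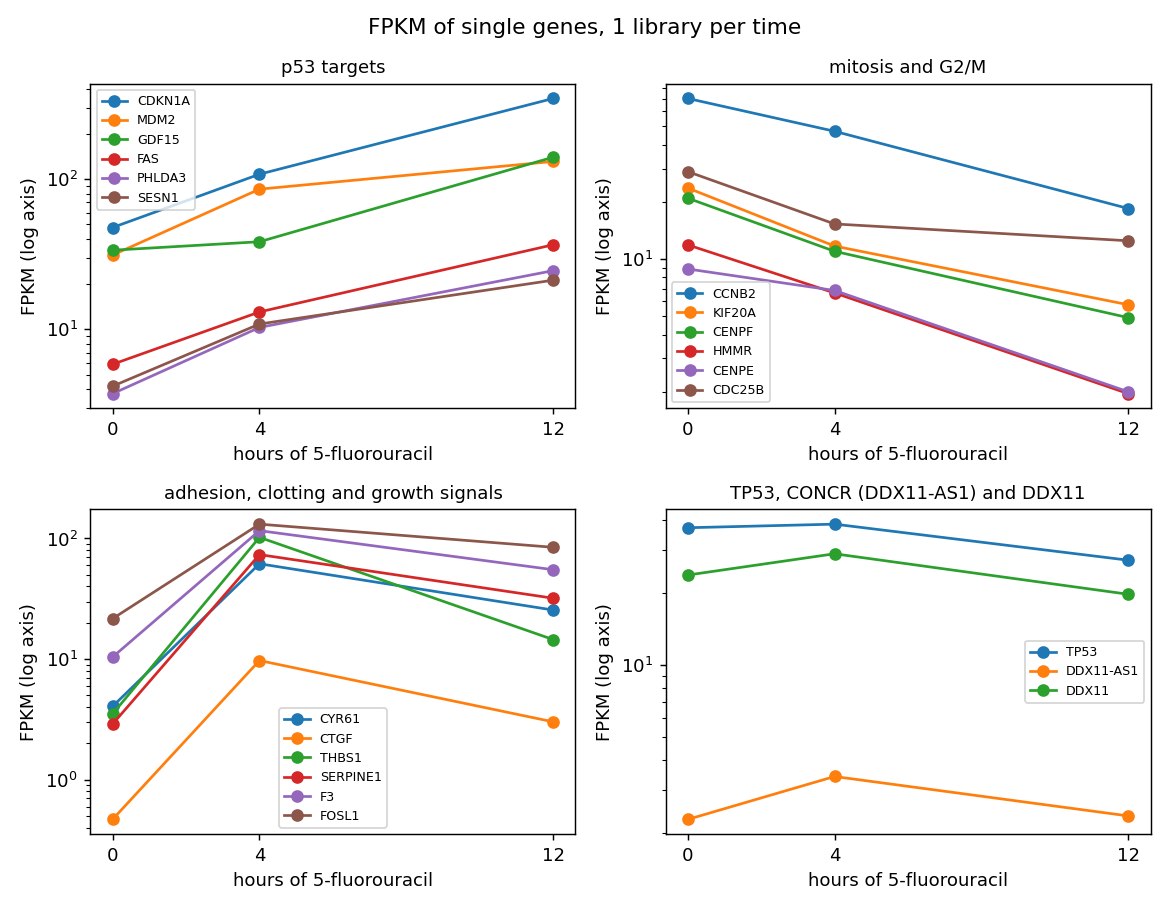
FPKM on log axes of single genes at 0 h, 4 h and 12 h of 5-fluorouracil, with 1 library per time and lines only to join the points of a gene. CDKN1A lies at 47.7, 108 and 345 FPKM, CCNB2 at 70.3, 47.2 and 18.5, and CYR61 at 4.05, 61.7 and 25.5.

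Over all named loci, 874 were at least 2-fold higher and 769 lower at 12 h than at 0 h, of 15042. With small-RNA genes left out and totals made equal the split was 629 higher and 1637 lower. Among protein-coding genes on 1 expressed locus, 365 were higher and 441 lower, of 9375.

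The third comparison set 12 h against 4 h. In the libraries labelled p53 knockout, 9 of 36 p53 targets were at least 2-fold higher at 12 h than at 4 h and 0 lower, and 11 of 42 mitosis genes were lower and 0 higher. GDF15, a secreted stress factor, was at 38.3 FPKM at 4 h and 140 at 12 h, and CDKN1A at 108 and 345. Of 33 immediate early genes, 2 were higher and 5 lower, with CYR61 at 61.7 and 25.5 FPKM and CTGF at 9.74 and 3.02. The p53 target median was 0.71 (0.84 relative to the shift of -0.13, percentile 100) and the mitosis median -0.61 (-0.48 relative, percentile 0). Cytosolic ribosomal proteins had a median of 0.26 (0.39 relative, percentile 100), with RPS27A at 8.09 and 17.1 FPKM, which is a log2 ratio of 0.99. Recombination and Fanconi repair lay at -0.35 (-0.22 relative, percentile 1.24), and the ATF4 list at -0.41 (-0.28 relative, percentile 0.65), with SLC7A11, a cystine transporter gene, at 17.6 and 2.87 FPKM. Apoptosis regulators lay at 0.068 (0.20 relative, percentile 97.63), and all other lists fixed beforehand lay inside the random range. Among the lists outside it, intervals over genes included 0 only for the ATF4 list (-0.52 to 0.12) and apoptosis regulators (-0.27 to 0.35).

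Gene span moved with this comparison too. The median log2 ratio went from 0.18 under 10 kb to -0.42 over 260 genes of 300 kb or more. With span and transcript length matched as well, ribosomal proteins lay at percentile 95.23, apoptosis regulators at 94.45 and recombination and Fanconi repair at 13.82, all inside the random range. Over all named loci, 578 were at least 2-fold higher and 750 lower, of 14851, against 738 and 527 after centring on the median. Leaving out small-RNA genes with totals made equal gave 710 and 619, and upper-quartile scaling gave 693 and 558.

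**Figure D3:**
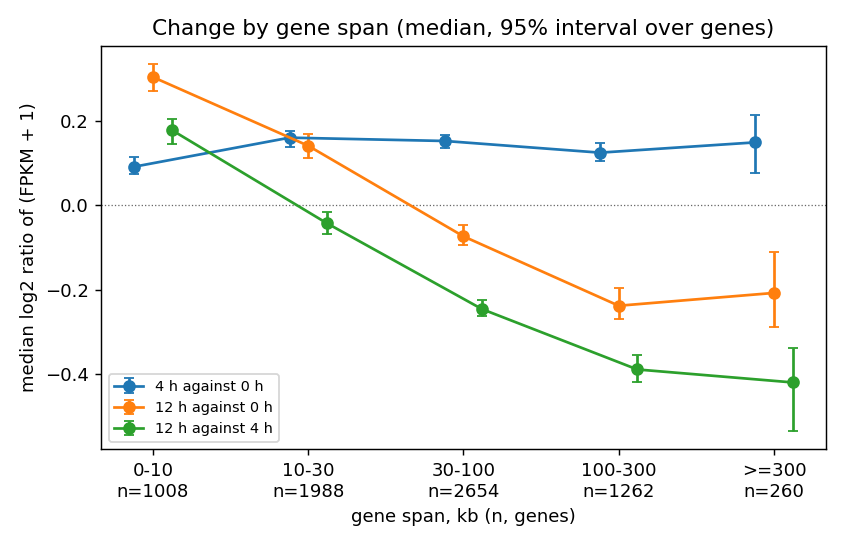
Median log2 ratio of (FPKM + 1) of protein-coding genes on 1 expressed locus against gene span in kb, for each pair of libraries, with 95% bootstrap intervals over genes and the number of genes under each bin. The 12 h against 4 h medians go from 0.18 to -0.42, and the 4 h against 0 h medians lie between 0.091 and 0.16.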

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

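The matching on gene and transcript length in this part was chosen after the data were seen. The bounds for the tests of span and transcript length were written before those tests were run. These tests were not among the analyses planned before the data were examined. Cytosolic ribosomal protein genes stood on opposite sides of their random lists at the 2 treated times, with a median log2 ratio against 0 h of 0.062 at 4 h (percentile 0.09) and 0.36 at 12 h (percentile 100). The difference was not tested, and with length matched as well the coding members on 1 expressed locus lay at percentile 2.33 at 4 h and 95.87 at 12 h, the latter inside the random range. Coding genes on 1 expressed locus that were at least 2-fold higher at 4 h and at least 2-fold lower at 12 h than at 0 h numbered 1. This gene was FER, a tyrosine kinase gene named after its values were seen, at 11.3, 24.1 and 4.95 FPKM at 0 h, 4 h and 12 h. The reverse order was found for 0 genes. Loci without a gene name, which enter the counts only as an alternative chosen after the data were seen, had a median log2 ratio of 0.72 at 4 h and 0.25 at 12 h against 0 h, over 159 and 156 loci at 5 FPKM or more in both libraries.

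Long genes were lower at 12 h than at 4 h, and this moved with several gene groups. Across 7172 coding genes, which are not independent replicates, the partial rank correlation of the log2 ratio with gene span was -0.19 (95% interval -0.21 to -0.17) with transcript length held constant. With transcript length, span held constant, it was -0.26 (-0.28 to -0.24). Both values are what each explanation needs, so slower or blocked elongation over long genes, and a length effect on mature RNA such as RNA integrity or length normalization, both stay open and may act together. For 4 h against 0 h the same correlations were -0.029 and 0.063, and an effect of 12 h of drug stays open as untested.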

How the results depend on the processing

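Of 72 recomputed counts, 38 stayed within 1.5 times the main count and 34 did not, and of 558 recomputed list medians 500 stayed inside their interval over genes or had none, 54 left it, and 4 changed sign in a list that stood outside its random range. Sign changes of any kind numbered 60, of which 56 were in lists inside their random range and 23 came with small-RNA genes left out. That scaling put the median log2 ratio of named loci at -0.23 at 4 h and -0.22 at 12 h against 0 h. For 12 h against 4 h it was -0.032. The minimum of 0 FPKM gave the same counts by construction. No group has a replicate, and the unknown depth limits the reading of low values. The causes of the changes were not tested, except that counts move by construction with the fold, the pseudocount and the features counted. Coding genes on 1 expressed locus, unnamed loci, zeros left out and length matching were chosen after the data were seen. Some lists left the random range once cut to coding members on 1 expressed locus and matched also on length. Against 0 h these were colon markers (99.59), cholesterol synthesis (0.76) and the ATF4 list (0.09) at 12 h and recombination and Fanconi repair (99.23) at 4 h. For 12 h against 4 h these were immediate early genes (1.36) and replication licensing and fork (0.85). The cut and the matching were not separated. Colon markers went from 13 to 7 members, and their 12 h median from 0.29 to 0.66. Over its settings, the p53 target median at 12 h against 0 h ran from 1.21 to 1.63 and that of mitosis genes from -1.16 to -0.87, with 1 direction each.

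With pseudocount 0.1, counts were 761 lower for 4 h against 0 h, 1403 lower for 12 h against 0 h, 945 higher for 12 h against 4 h, 1222 lower for 12 h against 4 h. With pseudocount 5, counts were 349 higher for 4 h against 0 h, 108 lower for 4 h against 0 h, 351 higher for 12 h against 0 h, 222 lower for 12 h against 0 h, 194 higher for 12 h against 4 h, 313 lower for 12 h against 4 h. With a minimum of 5 FPKM, counts were 183 lower for 4 h against 0 h, 308 higher for 12 h against 4 h. With median centring, counts were 527 lower for 4 h against 0 h. With small-RNA genes left out and total rescaled, counts were 431 higher for 4 h against 0 h, 907 lower for 4 h against 0 h, 1637 lower for 12 h against 0 h. With a 1.5-fold threshold, counts were 1996 higher for 4 h against 0 h, 1082 lower for 4 h against 0 h, 2302 higher for 12 h against 0 h, 2349 lower for 12 h against 0 h, 1425 higher for 12 h against 4 h, 2550 lower for 12 h against 4 h. With a 3-fold threshold, counts were 235 higher for 4 h against 0 h, 118 lower for 4 h against 0 h, 304 higher for 12 h against 0 h, 146 lower for 12 h against 0 h, 237 higher for 12 h against 4 h, 179 lower for 12 h against 4 h. With protein-coding genes on 1 expressed locus, counts were 315 higher for 4 h against 0 h, 111 lower for 4 h against 0 h, 365 higher for 12 h against 0 h, 441 lower for 12 h against 0 h, 155 higher for 12 h against 4 h, 376 lower for 12 h against 4 h.

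With small-RNA genes left out and total rescaled, medians for 4 h against 0 h were -0.20 for nucleotide metabolism, -0.14 for replication licensing and fork, 0.12 for G1/S regulators, -0.73 for mitosis and G2/M, -0.33 for sister chromatid cohesion, -0.15 for recombination and Fanconi repair. Further such medians were -0.31 for ATF4 and unfolded protein stress, -0.27 for heat shock, -0.27 for interferon response, -0.013 for apoptosis regulators, -0.030 for snoRNA host genes, 0.022 for ribosome biogenesis. Further such medians were -0.20 for RNA exosome and nuclear RNA decay, -0.33 for cytosolic ribosomal proteins, -0.49 for cholesterol synthesis, -0.16 for colon epithelial markers, -0.24 for long-lived housekeeping transcripts. With small-RNA genes left out and total rescaled, medians for 12 h against 0 h were -0.18 for nucleotide metabolism, -0.26 for replication licensing and fork, 0.048 for G1/S regulators, -0.38 for recombination and Fanconi repair, -0.27 for heat shock, 0.13 for NF-kB targets and cytokines. Further such medians were 0.069 for apoptosis regulators, -0.081 for snoRNA host genes, 0.056 for ribosome biogenesis, 0.068 for cytosolic ribosomal proteins, -0.49 for cholesterol synthesis, -0.15 for long-lived housekeeping transcripts. With median centring, medians for 12 h against 4 h were 0.043 for nucleotide metabolism, 0.013 for heat shock, 0.073 for ribosome biogenesis, 0.39 for cytosolic ribosomal proteins. With upper-quartile scaling, medians for 12 h against 4 h were 0.039 for nucleotide metabolism, 0.010 for heat shock, 0.073 for ribosome biogenesis, 0.38 for cytosolic ribosomal proteins. With median centring, medians for 4 h against 0 h were 0.099 for replication licensing and fork, -0.50 for mitosis and G2/M, -0.11 for sister chromatid cohesion, 0.065 for recombination and Fanconi repair, 0.18 for snoRNA host genes, 0.24 for ribosome biogenesis. Further such medians were 0.043 for RNA exosome and nuclear RNA decay, -0.093 for cytosolic ribosomal proteins, -0.25 for cholesterol synthesis. With upper-quartile scaling, medians for 4 h against 0 h were 0.12 for replication licensing and fork, -0.47 for mitosis and G2/M, -0.082 for sister chromatid cohesion, 0.097 for recombination and Fanconi repair, 0.27 for ribosome biogenesis, 0.066 for RNA exosome and nuclear RNA decay. Further such medians were -0.068 for cytosolic ribosomal proteins, -0.23 for cholesterol synthesis. With small-RNA genes left out and total rescaled, medians for 12 h against 4 h were -0.016 for heat shock, 0.36 for cytosolic ribosomal proteins. With coding members on 1 expressed locus, matched also on length, medians for 4 h against 0 h were 0.35 for interferon response. With coding members on 1 expressed locus, matched also on length, medians for 12 h against 0 h were 0.22 for interferon response.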

Other observations

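The lists of YAP and SRF targets and the sum over fibroblast markers in this part were chosen after the leading genes had been seen, as was the test of the p53 target list against its label. Some single genes, chosen after their values were seen, were higher at 4 h than at 0 h. THBS1, a matrix glycoprotein gene, was at 3.51 FPKM at 0 h, 102 at 4 h and 14.5 at 12 h, and SERPINE1, the plasminogen activator inhibitor gene, at 2.89, 73.5 and 32.0. F3, tissue factor, was at 10.4, 116 and 55.1 FPKM, the focal adhesion gene VCL at 65.7, 266 and 34.9, and the integrin gene ITGA2 at 15.3, 45.8 and 8.70. At 12 h the epithelial keratin genes KRT8 (286 FPKM at 0 h and 805 at 12 h), KRT18 (109 and 258) and KRT19 (205 and 443) were at least 2-fold higher. The vitamin D hydroxylase gene CYP24A1 (133 and 29.6 FPKM), the urea cycle gene CPS1 (18.5 and 3.19) and the RNA-binding protein gene QKI (133 and 26.8) were lower.

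Some loci carried values that look like multiples of 1 unit. At 4 h, 5 loci were listed at exactly 2158 FPKM, and this value was taken as the unit after it had been seen. Of the 74 other loci near or above it, 16 lay at a multiple of 0.5 of the unit, with a tolerance of 0.02 of that step, against 2.96 if spread evenly. Exact values were also repeated at 0 h, with 181 FPKM at 6 loci, 1288 at 3 and 2576 at 4, FGF13 among the last. At 12 h, 323 FPKM stood at 4 loci. Multiples were not examined at those times. The coding gene MYBL1 was at 10.7, 10805 and 26.2 FPKM at 0 h, 4 h and 12 h. Its 4 h value also lies near a multiple of the 4 h unit, so its ratio is not read as a change in expression. MYBL1 is among the coding genes on 1 expressed locus, so the counts of that class hold such values too.

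Target genes of p53 were higher after treatment in libraries labelled p53 knockout. The fixed ATF4 and unfolded protein list lay at percentile 19.3 at 12 h, which argues against a rise of that list as a whole. Of its 31 genes, 2 were at least 2-fold higher at 12 h than at 0 h and 2 lower. SESN2 was at 3.53 and 14.4 FPKM and SLC7A11 at 15.5 and 2.87. Targets shared with p53 were not tested apart from the list. A mislabelled sample or file, with working p53 in the cells, cannot be told apart from other routes to these genes, since all 3 libraries carry 1 label and the percentile of 100 of the p53 target list is the observation itself and no test of it. The column headers that begin with WT are separate from the values and leave it open. TP73 reached 4.42 FPKM, so p73 acting in place of p53 is a further open explanation, although TP73 itself was at 4.41, 3.61 and 4.42 FPKM at 0 h, 4 h and 12 h. An effect of the drug through another route was not tested.

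Targets of YAP and of SRF were higher at 4 h than at 0 h, which may be a coordinated rise, with a median log2 ratio of 1.16 for YAP targets and 0.63 for SRF and actin cytoskeleton genes (percentile 100 each). At 12 h against 0 h the medians were 0.78 (percentile 100) and 0.34 (percentile 99.84). The 46 measured members not seen before the lists were written had a median of 0.70 at 4 h (percentile 100) and of -0.37 for 12 h against 4 h (percentile 0.21). Scaling of the 4 h library is argued against, since their centred median was 0.54. These members include TAGLN and SRF, which are also on the fixed fibroblast and immediate early lists. The YAP and SRF lists were written after the leading genes had been seen, so the percentile of 100 is no independent check. For fibroblast-like cells, the test whose bounds were written before it was run did not decide. At 4 h, 5 of 15 listed markers reached 1 FPKM, which that explanation needs. COL1A1 was at 1.11 FPKM, between its bounds of 1 and 10. The 7 markers in the table summed to 11.1 FPKM at 0 h and 17.4 at 4 h, with TAGLN at 1.55 and 8.91. Without the 2 that are also on the SRF list the sum was 4.93 and 4.51, a difference of -0.42. The 55 YAP and SRF targets summed to 3738 FPKM at 0 h and 7699 at 4 h. Those markers were low and each time has 1 library, so the sum cannot decide and such cells stay open. A response to the drug and one to handling or fresh medium also stay open, both untested.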
